A study of Labeotropheus fuelleborni and Maylandia zebra with 12 samples.

How the data were processed

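RNA was measured in 2 oral tissues of 2 Lake Malawi cichlid fishes, Labeotropheus fuelleborni and Metriaclima (Maylandia) zebra. The replacement tooth samples were unerupted teeth taken from bony crypts of the jaw, and the taste bud samples were a strip of epithelium lying on the lip side of the outermost teeth of the lower jaw, per the labels' protocols. RNA was turned into libraries with a stranded mRNA kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols. Each species and tissue had 3 libraries, so that 12 libraries fell into 4 groups. Replicate numbers were taken from the sample titles. The labels call the libraries replicates without saying whether each came from a separate animal, so p-values measure the spread between these samples, which may be partly technical.

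The authors deposited a table of read counts per gene feature, with 1 column per library and no normalization, and the count unit was checked on the values, which were whole numbers with totals that differed between libraries. The submitters' processing notes name TopHat2 2.0.9, SAMtools 0.19, HTSeq 0.6.1, edgeR 3.6.8 and limma 3.20.9, with no role or order. The genome build, the annotation and the strand setting used in counting are not given in the sources used here. The table held 26490 features, of which 10619 carried a gene name and 15871 only a locus number that the table does not pair with a name. No count was found in any library for 5798 features. There was no line for unassigned reads.

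Total counts per library ranged from 72226 to 300663, so that 1 count was worth 3.33 to 13.8 CPM, the usual unit of counts relative to the library total. A total of this size limits precision for genes of low expression, and a threshold of 1 CPM amounted to at least 1 count. Pairs of libraries within a group were compared over genes with at least 10 counts. Their chi-square per degree of freedom ranged from 2.81 to 17.6, above sampling noise for every pair, so that no pair was treated as repeats of 1 library. This does not show that the libraries are separate biological replicates.

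Differential expression was computed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups (minimum count 10 in at least 3 libraries after scaling for depth, minimum total 15), which left 2962 genes. TMM factors, a dispersion trend and a quasi-likelihood model with 4 group means were fitted to all 12 libraries, without a replicate block, and 6 contrasts were tested: tooth against taste bud as the mean of both species, the same within each species, L. fuelleborni against M. zebra within each tissue, and the difference between species in the tissue difference. Adjusted p-values are Benjamini-Hochberg values over the 2962 genes of a contrast, two-sided, with a threshold of 0.05. Log2 fold changes (log2FC) are model estimates with their standard errors (SE). CPM values use TMM library sizes and are given as mean ± SD. A fold is the ratio of summed counts over summed TMM library sizes. Where all libraries of a tissue had 0 counts, the fold is a lower bound against 3 counts over that tissue. With 1 to 3 counts in a tissue, the ratio is given with its 95% counting interval. These bounds and intervals cover counting error only.

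Before the data were examined, 23 gene lists were fixed: tooth mineral matrix, tooth patterning regulators, taste receptor cell, oral keratinocyte, mucous cell, ionocyte, epithelial stem and progenitor, the BMP, Wnt, Hedgehog, FGF and Notch pathways, osteoclast, cartilage, skeletal muscle, erythrocyte, immune cell, Schwann cell and nerve, pigment cell, endothelium, cell cycle, stress response and mitochondrial respiration. A feature belonged to a list when its name matched the symbol, alone or with a teleost copy suffix. Members were counted from the edgeR test, adjusted over all genes and again over the list alone. Some lists had few members above the filter. Of those in the table, 3 of 20 passed it for taste receptor cell, 4 of 22 for epithelial stem and progenitor, and 7 of 32 for tooth patterning. A gene could pass the filter through the libraries of one group alone, so counts of tested members do not speak for a whole list. The 10 lists with at least 3 tested members were tested with camera (limma 3.58.1, voom values, preset inter-gene correlation 0.01), adjusted over the lists of a contrast. Camera with an estimated correlation and fry were alternatives. Camera takes no block, so with the replicate number as a random block its pre-ranked form was run on the gene statistics of that fit.

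Genes named in the text were chosen by a rule fixed at the same time. For the tissue comparison these were the 10 named genes with the highest absolute log2FC in each direction, among those past the threshold, with an average log2 CPM of at least 3, whose libraries of one tissue all lay above those of the other tissue within each species. For each species comparison they were the 5 such genes in each direction, and for each list its 4 tested members with the smallest p. A fixed panel of genes was given whatever the result: sox2, pitx1, shh, bmp2, bmp4, sostdc1, lef1, tp63, lgr5, lgr6, celsr1, gli1, sp7, trpm5, calhm1, plcb2, igfbp5, foxi1 and krt15. The last 3 had no feature by that name in the table used here. Some genes that these rules select are not reported here. Genes counted as expressed in both tissues had at least 1 CPM in all 12 libraries.

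The procedure was tested on simulated counts for the 2962 genes, with the library sizes of the real samples. Each gene had 1 mean, pooled over all 12 libraries, before its change was added. Genes at or near 0 counts in 1 tissue, such as phex, were thus not simulated at that level. The shares recovered may be too high for such genes. In the tissue comparison 10.4% of genes changed 2-fold, 82.1% of those changed 4-fold and 97.0% of those changed 8-fold were recovered, and 3.08% of calls were false. In the tooth and taste bud species comparisons 34.3% and 35.8% of genes changed 4-fold and 83.3% and 80.3% of those changed 8-fold were recovered. In the test of the difference between species in the tissue difference, 2.99% of genes changed 4-fold and 21.2% of those changed 8-fold were recovered. A list changed 4-fold was called in 20 of 20 simulated data sets, and 0 of 200 tests of unchanged lists passed. The simulated genes were drawn independently of each other. In the real tissue comparison the correlation between genes was estimated at 0.556 for the tooth mineral matrix list. The simulation therefore does not show how often the list test errs when genes are correlated.

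Alternatives were DESeq2 1.42.0, limma-voom, size factors of the DESeq2 type, library size alone, no filter, a filter of 1 CPM in 3 libraries, a robust fit, a log2FC limit of 1, the replicate number as a block, fits on the compared libraries only and leaving out each library in turn. After seeing the data, 3 more were added: leaving out the 3 libraries with the highest share of counts at ribosomal protein genes, that share as a covariate, and a threshold of 50 CPM. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.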

Results

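The transcriptomes of replacement teeth and of taste bud-bearing oral epithelium were compared in the cichlids L. fuelleborni and M. zebra, with 3 libraries per species and tissue. The counts at gene features were few for whole transcriptomes. Totals were 111626, 122957 and 300663 in L. fuelleborni tooth (replicates 0, 3 and 4) and 220903, 248332 and 147480 in L. fuelleborni taste bud (replicates 1, 2 and 4). In M. zebra they were 155864, 184675 and 196861 in tooth (replicates 0, 1 and 3) and 72226, 85872 and 111155 in taste bud (replicates 1, 2 and 3). An unnamed feature, LOC105941146, held 20.9% ± 7.88 (SD, n = 3) of all counts in L. fuelleborni taste bud and 19.6% ± 2.24 in M. zebra taste bud, against 0.351% ± 0.370 and 0.0890% ± 0.0352 in tooth. The first principal component carried 62.3% of the variance of log2 CPM and separated the 6 tooth libraries from the 6 taste bud libraries.

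The 65 ribosomal protein genes, which encode the protein part of the ribosome, held between 1.39% and 6.36% of the counts of a library. Their share differed within groups, from 2.34% to 6.31% in L. fuelleborni tooth and from 3.08% to 6.36% in L. fuelleborni taste bud. L. fuelleborni tooth replicate 4 and taste bud replicates 1 and 2 had the highest shares. The library kit marks strand, and the strand setting of the counting is not given in the sources used here. A count at a feature therefore cannot be assigned with certainty to that gene rather than to a gene on the opposite strand at the same place, and this holds for every gene named below.

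**Figure D1:**
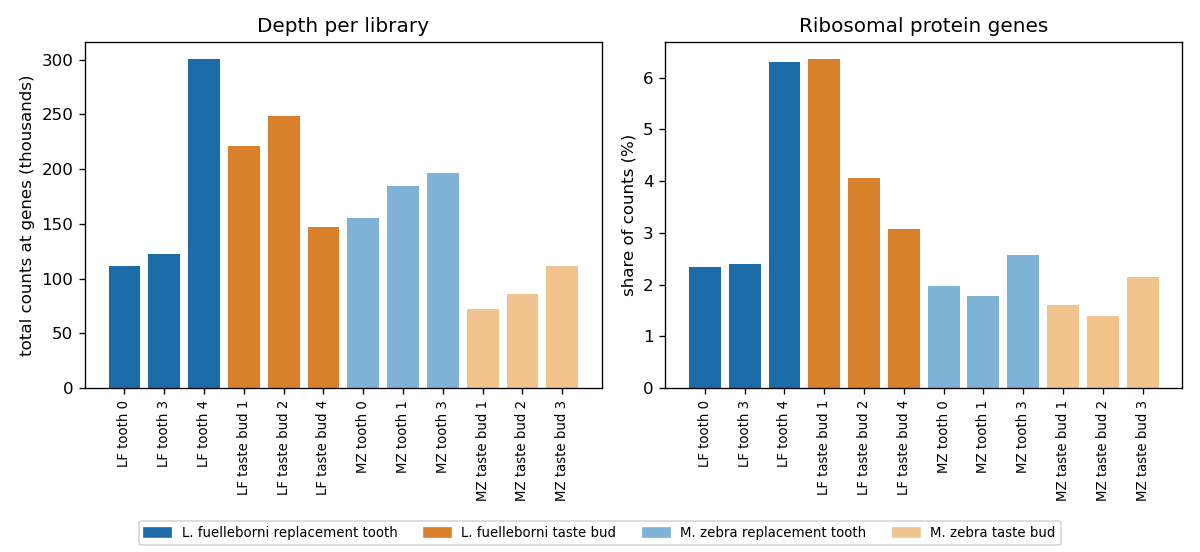
Bars give, for each of the 12 libraries, the total counts at genes (left) and the percentage of counts at 65 ribosomal protein genes (right), coloured by species and tissue, LF for L. fuelleborni and MZ for M. zebra. Totals ran from 72226 to 300663, and the ribosomal share from 1.39% to 6.36%.

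To find the genes that set tooth apart from taste bud, the tissues were compared over both species. All 12 tested genes of the tooth mineral matrix list were higher in tooth, and 9 of 12 tested oral keratinocyte genes were higher in taste bud, with 3 not past the threshold. Both lists passed the camera test with the preset correlation and missed the threshold with an estimated correlation (adjusted p = 0.1246 and adjusted p = 0.115). Type I collagen, the main protein of dentin and bone, was at 9659.9 ± 5547 CPM for col1a1 (SD, n = 6) in tooth and 185 ± 209.9 in taste bud, a ratio of means of 52.3 (log2FC 5.97, SE 0.55, adjusted p = 1.91e-09). The ratio of summed counts, in which deep libraries weigh more, was 81.7. The phosphate-regulating peptidase phex had 655 counts in tooth and 0 in taste bud, at least 140.0-fold higher. Transglutaminase tgm1, which crosslinks the envelope of cornifying keratinocytes, had 0 counts in tooth and 72 in taste bud, at least 37.4-fold higher in taste bud. In all, 1564 of 2962 genes tested (52.8%) passed the threshold with edgeR's quasi-likelihood test, 967 higher in tooth and 597 higher in taste bud. Without a filter on low counts, 3327 genes passed of 20692 tested. P-values of that fit are not comparable with those of the filtered fit. They were far smaller for some genes (afap1l2, adjusted p = 9.75e-52 against 1.06e-11) and larger for others (pdpr, 0.532 against 0.304).

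Of the 10 named genes with the largest differences in favour of tooth, 6 had no count in any taste bud library: phex, sp7, plod2, bgn, pitpnm3 and mmel1. The lower bounds were 60.9-fold for sp7 (osterix, a transcription factor of osteoblasts and odontoblasts), 95.4-fold for plod2 (a lysyl hydroxylase of collagen), 85.5-fold for bgn (biglycan, a matrix proteoglycan), 67.1-fold for pitpnm3 and 73.8-fold for mmel1. The adaptor gene afap1l2 was at 3680.0 ± 1407 CPM in tooth and 8.25 ± 8.48 in taste bud, 429-fold higher (log2FC 8.73, SE 0.59, adjusted p = 1.06e-11). Carbonic anhydrase ca12 had 1129 counts in tooth and 1 in taste bud, a ratio of 724 (129.7 to 28628), with the 95% interval in parentheses. The corresponding ratio was 259.6 (88.6 to 1260.4) for plekhd1. In the other direction, sycp1, which encodes a protein of the synaptonemal complex of meiosis, was 59.7-fold higher in taste bud (log2FC -5.98, SE 0.53, adjusted p = 9.08e-10). The retinoid-binding protein gene rbp7 was 101-fold higher and the cornified envelope gene scel had a ratio of 89.6 (24.3 to 749). Ratios in favour of taste bud were 144 (48.7 to 702) for hid1 and 31.2 (10.2 to 155) for the amino acid transporter slc7a5. They were 38.3-fold for nfrkb, 31.9-fold for prkaa2 (a catalytic subunit of AMP-activated kinase), 29.0-fold for lzic and 26.9-fold for lactb. By the rule that chose these genes, all libraries of one tissue lay above all libraries of the other within each species. The call of slc7a5 ended without the 3 libraries of highest ribosomal share (adjusted p = 0.143), which left 1 L. fuelleborni taste bud library, with a log2FC of -3.32 (SE 1.80) against -5.07 (SE 0.96) with all libraries.

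Among the lists fixed in advance, all 12 tested members of the tooth mineral matrix list were higher in tooth, among them alpl, col10a1, col1a1, col1a2, entpd5, fam20a, panx3, phex, phospho1, slc20a2 and sparc. All 12 also passed when adjusted over the list alone. Their median log2FC was 6.51, or 5.61 with the 6 genes that had no taste bud count set to their lower bound. The collagen-binding glycoprotein sparc was at 3594 ± 1875 CPM in tooth and 92.0 ± 122 in taste bud, a ratio of means of 39.0 and 57.1-fold by summed counts (log2FC 5.58, SE 0.57, adjusted p = 9.97e-09). For col1a2 these were 52.6 and 82.4-fold. The list passed the camera test (adjusted p = 1.01e-06), and adjusted p = 0.1246 with an estimated correlation. Of 7 tested tooth patterning regulators, 5 were higher in tooth, among them dlx6, lhx8, shh and sp7, and 2 did not pass (dlx3 and pitx1), while 6 passed when adjusted over the list alone. The homeobox gene lhx8 was 9.42-fold higher (log2FC 3.10, SE 0.54, adjusted p = 2.15e-05). The ratio was 50.03 (8.72 to 2001) for the ligand gene shh. The camera test gave adjusted p = 0.0128 for this list, and adjusted p = 0.115 with an estimated correlation.

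**Figure D2:**
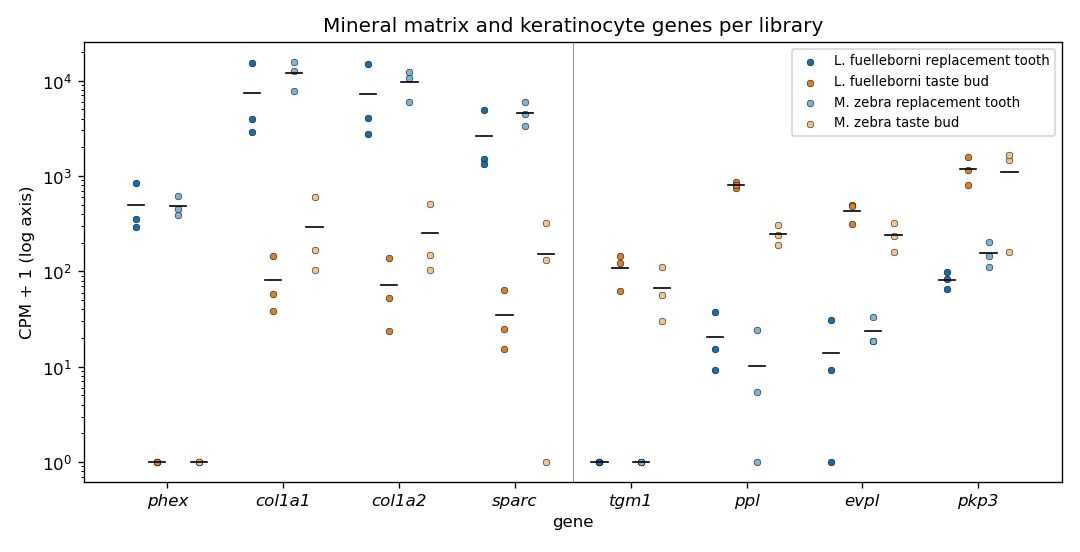
Points give CPM plus 1 on a log axis in each of the 12 libraries for 4 genes of the tooth mineral matrix list (phex, col1a1, col1a2, sparc) and 4 of the oral keratinocyte list (tgm1, ppl, evpl, pkp3), coloured by species and tissue, and black bars are the means of 3 libraries. In tooth, phex averaged 491 CPM against 0 in taste bud, and tgm1 averaged 86.9 CPM in taste bud against 0 in tooth.

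Of the 12 tested oral keratinocyte genes, 9 were higher in taste bud (anxa1, esrp1, evpl, itgb4, perp, pkp3, ppl, tgm1 and tp63) and 3 did not pass, dsp and lama3 among them, while 11 passed when adjusted over the list alone. The plakins periplakin and envoplakin, which link desmosomes to keratin, were 35.8-fold higher for ppl (log2FC -4.84, SE 0.49, adjusted p = 7.52e-09) and 17.6-fold higher for evpl. The desmosomal gene pkp3 was 10.3-fold higher. The median log2FC of the list was -2.35. It passed the camera test (adjusted p = 5.44e-05), and adjusted p = 0.115 with an estimated correlation. Of 3 tested taste receptor cell genes, 2 were higher in taste bud. The decarboxylase gene ddc, needed for serotonin synthesis, was 24.9-fold higher, and trpm5, the cation channel of taste transduction, was at 2050.3 ± 1099.9 CPM in taste bud and 649 ± 153 in tooth, 2.81-fold higher (log2FC -1.53, SE 0.32, adjusted p = 2.23e-04). The third, itpr3, a calcium release channel of taste cells, was 5.61-fold higher in tooth. Its call ended without the 3 libraries of highest ribosomal share (adjusted p = 0.0584), with a log2FC of 1.83 (SE 0.77) against 2.90 (SE 0.72). The camera test of this list gave adjusted p = 0.253. The counts of plcb2 were 32 in tooth and 2 in taste bud, a ratio of 10.3 (2.62 to 88.4), and calhm1 had 0 and 1. Both were too low to be tested. In the fit without a filter, whose p-values are not comparable with those of the filtered fit, plcb2 passed (adjusted p = 0.00453).

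Signalling pathways that act in tooth renewal were compared next. Of the members in the table, 4 of 15 Hedgehog, 6 of 38 Wnt and 5 of 30 BMP genes passed the filter. Tooth counts alone could satisfy that filter, so the tested genes do not speak for the whole pathways. All 4 tested Hedgehog genes, among them shh, its receptor ptch1 and the transcription factor gli1, were higher in tooth, also when adjusted over the list alone. The transcription factor gene gli1 was 15.7-fold higher (log2FC 3.66, SE 0.63, adjusted p = 1.89e-05), and the ratio was 89.2 (15.7 to 3547) for ptch1. Of 6 tested Wnt genes, 5 were higher in tooth (ctnnb1, frzb, rspo1, tcf7 and znrf3), as many as over the list alone, and rspo3 did not pass. The beta-catenin gene ctnnb1 was 5.41-fold higher, the Wnt receptor ligase gene znrf3 was 5.80-fold higher, and frzb, a secreted Wnt antagonist, had a ratio of 245 (43.7 to 9703). For rspo1 the ratio was 65.4 (11.5 to 2609). The camera test gave adjusted p = 0.0128 for Hedgehog, with adjusted p = 0.1246 with an estimated correlation. For Wnt it gave adjusted p = 0.0197, with adjusted p = 0.115 with an estimated correlation. Without L. fuelleborni tooth replicate 4 it gave adjusted p = 0.0554 over the 12 lists then tested and 0.0462 over the same 10 lists. Of 5 tested BMP genes, 4 were higher in tooth (acvr1, bambi, bmp6 and fstl1), as many as over the list alone, and id1 did not pass. The ligand gene bmp6 was at 2689.6 ± 792 CPM in tooth and 1315 ± 538 in taste bud, 1.95-fold higher, and the follistatin-like gene fstl1 was 18.6-fold higher. The ratios were 31.1 (8.38 to 261) for bambi and 13.9 (4.55 to 69.1) for acvr1. The call of acvr1 ended without the 3 libraries of highest ribosomal share (adjusted p = 0.137), with a log2FC of 2.11 (SE 1.13) against 3.35 (SE 0.81). The BMP list missed the threshold in the camera test (adjusted p = 0.0542), and passed in 10 of the 12 fits that left out a library (0.0178 to 0.0418), all but those without L. fuelleborni tooth replicate 4 or M. zebra tooth replicate 3 (0.0482 and 0.0489 over the same 10 lists), and without the 3 libraries of highest ribosomal share (adjusted p = 0.0306). With an estimated correlation and all libraries, the camera test of the BMP list gave adjusted p = 0.1246. The ligand genes bmp2 and bmp4 and the antagonist gene sostdc1 had 22, 27 and 25 counts in tooth and 0 in taste bud. They were at least 4.70-fold, 5.77-fold and 5.35-fold higher in tooth, and were below the filter for testing. In the fit without a filter their adjusted p-values were 0.00602, 0.00231 and 0.00277, which are not comparable with those of the filtered fit.

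Of 2 tested FGF genes, the receptor gene fgfr2 was 2.34-fold higher in tooth (adjusted p = 0.0208) and fgf2 did not pass (adjusted p = 0.194), as over the list alone. The call of fgfr2 ended in 4 fits that left out a library (adjusted p 0.0523 to 0.0796): L. fuelleborni tooth replicate 4, L. fuelleborni taste bud replicates 2 and 4 and M. zebra taste bud replicate 2. Of 3 tested Notch genes, the target gene nrarp was 2.54-fold higher in tooth (adjusted p = 0.0111), while dld (adjusted p = 0.313) and jag1 (adjusted p = 0.728) did not pass, and the camera test gave adjusted p = 0.614. Without the 3 libraries of highest ribosomal share, nrarp missed the threshold (adjusted p = 0.0776), with a log2FC of 1.33 (SE 0.60) against 1.47 (SE 0.48) with all libraries. In that fit fgf2 passed (log2FC -1.03, SE 0.37, adjusted p = 0.0271), against -0.56 (SE 0.36) with all libraries.

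Genes known from epithelial stem and progenitor cells were examined because the study is about renewal. Of 4 tested members, 2 were higher in tooth, gli1 among them, tp63, the transcription factor of basal keratinocytes, was 6.67-fold higher in taste bud (log2FC -2.50, SE 0.47, adjusted p = 6.05e-05), and pitx1 did not pass (154 ± 60.5 CPM in tooth, 86.4 ± 35.5 in taste bud, adjusted p = 0.0727). Adjusted over the list alone, pitx1 passed as well, so that 3 were higher in tooth and 1 in taste bud. The call of pitx1 over all genes also passed without L. fuelleborni tooth replicate 0 (adjusted p = 0.0391) and with the ribosomal share as a covariate (adjusted p = 0.0354). The camera test gave adjusted p = 0.519. The remaining panel genes were too low to be tested. The counts of sox2, a transcription factor of taste and dental progenitors, were 13 in tooth and 19 in taste bud (9.95 ± 7.40 and 21.3 ± 14.5 CPM), with adjusted p = 0.556 in the fit without a filter. Those of lgr6, a receptor of epithelial stem cells, were 42 and 2, a ratio of 13.5 (3.504 to 115). In that fit, whose p-values are not comparable with those of the filtered fit, lgr6 passed (adjusted p = 0.00128). The ratios were 4.81 (1.12 to 43.4) for lef1, 4.06 (1.20 to 21.4) for celsr1 and 1.07 (0.208 to 6.88) for lgr5, which had 5 and 3 counts. In the same fit lef1 (adjusted p = 0.175), celsr1 (adjusted p = 0.106) and lgr5 (adjusted p = 0.9998) did not pass, and the ratios' intervals cover counting error only.

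Markers of other cell types that a dissected tooth or lip strip could hold were given the same test. Of single tested members, the integrin gene itgb3 of the osteoclast list had 108 counts in tooth and 0 in taste bud, at least 23.1-fold higher, and the tight junction gene cldn5 of the endothelium list had a ratio of 81.5 (14.4 to 3243). The Schwann cell and nerve list had 2 tested members that went apart, the myelin gene mpz higher in tooth with a ratio of 19.5 (6.45 to 96.1) and the neuregulin receptor gene erbb3 16.6-fold higher in taste bud. In the immune list cd74 did not pass (189 ± 207 CPM in tooth, 229 ± 285 in taste bud, adjusted p = 0.793). Without the 3 libraries of highest ribosomal share, cd74 was higher in taste bud (log2FC -1.18, SE 0.45, adjusted p = 0.0364), against 0.18 (SE 0.51) with all libraries. The thymidylate synthase gene tyms of the cell cycle list was 3.17-fold higher in tooth and the citrate synthase gene cs of the mitochondrial list 3.71-fold higher. The call of cs ended without the 3 libraries of highest ribosomal share (adjusted p = 0.0947), with a log2FC of 1.38 (SE 0.66) against 1.71 (SE 0.53). The mucous cell gene creb3l1 (adjusted p = 0.430) and the muscle gene ryr3 (adjusted p = 0.319) did not pass. Of 5 stress response genes, klf2 was 5.35-fold and ddit3 2.21-fold higher in taste bud, fosb, hspa8 and ier2 did not pass, the same 2 passed over the list alone, and the camera test gave adjusted p = 0.104. The call of ddit3 ended without M. zebra tooth replicate 0 or 1 (adjusted p 0.0511 to 0.0582), and ier2 passed without L. fuelleborni tooth replicate 4, L. fuelleborni taste bud replicate 4 or M. zebra taste bud replicate 2 (adjusted p 0.0188 to 0.0348), as it did with the ribosomal share as a covariate (adjusted p = 0.0448). Without the 3 libraries of highest ribosomal share, ddit3 missed the threshold (adjusted p = 0.195), with a log2FC of -0.89 (SE 0.55) against -1.22 (SE 0.43). The ionocyte, cartilage, erythrocyte and pigment cell lists had 0 members above the filter, with summed counts of 109, 33, 65 and 112 in tooth and 17, 21, 15 and 66 in taste bud.

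The tissue difference was then tested within each species. In L. fuelleborni 1142 genes passed, 730 higher in tooth and 412 higher in taste bud, and in M. zebra 1262 passed, 797 and 465. In L. fuelleborni 11 of the 12 tested mineral matrix genes were higher in tooth, with slc20a2 not past the threshold, and in M. zebra all 12 were. Of the 7 tooth patterning regulators, 4 were higher in tooth in L. fuelleborni and 5 in M. zebra. Of the 12 oral keratinocyte genes, 9 were higher in taste bud in L. fuelleborni and 7 in M. zebra, where itgb4 and perp did not pass. Of the 3 taste receptor cell genes, ddc alone passed in L. fuelleborni, and all 3 passed in M. zebra. The log2FC of trpm5 was -0.83 (SE 0.45, adjusted p = 0.152) in L. fuelleborni and -2.24 (SE 0.47, adjusted p = 4.02e-04) in M. zebra, and the test of the difference gave adjusted p = 0.636. For itpr3 these were 1.87 (SE 0.79, adjusted p = 0.0633) and 3.92 (SE 1.21, adjusted p = 0.0109), and 0.738 for the difference. Hedgehog genes higher in tooth numbered 4 of 4 in either species, Wnt genes 4 and 5 of 6, BMP genes 4 and 3 of 5, and FGF and Notch genes 0 in either. Without a filter on low counts, 1881 genes passed in L. fuelleborni. Genes higher in tooth in both species numbered 600, against 196.4 for independent lists, and genes higher in taste bud in both numbered 299, against 64.7. No gene was called in opposite directions. Across genes, which are not independent replicates, the log2FC of the species correlated with Pearson's r = 0.88 and Spearman's rho = 0.85, and 1432 of the 1505 genes called in either species (95.1%) had the same direction. Without the 3 libraries of highest ribosomal share, all of them from L. fuelleborni, 744 genes passed in that species, 355 higher in tooth and 389 higher in taste bud. This alternative was chosen after seeing the data and left L. fuelleborni taste bud with 1 library, assumed to vary like the other groups.

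**Figure D3:**
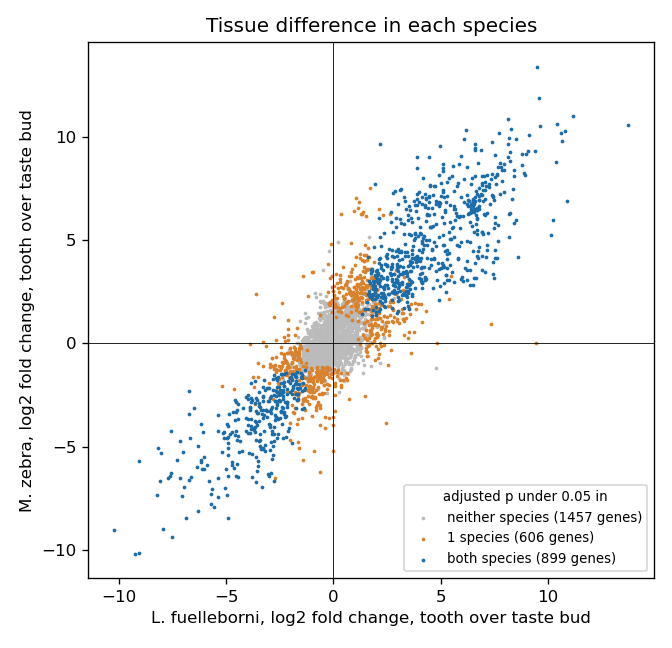
Each point is one of 2962 genes, with its log2 fold change of tooth over taste bud in L. fuelleborni on the horizontal axis and in M. zebra on the vertical axis, coloured by whether adjusted p was under 0.05 in neither, 1 or both species. Points lie along the diagonal, with r = 0.88 across genes.

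To ask whether the tissue difference itself depended on the species, the species difference in log2FC was tested directly. With edgeR, 0 of 2962 genes passed, and the smallest adjusted p was 0.189. At an unadjusted p under 0.05 there were 228 genes, against 148.1 from chance alone. DESeq2 also called 0 genes, with 220 at an unadjusted p under 0.05, and limma-voom, with 260 at an unadjusted p under 0.05, called 1, LOC101470201, singled out after its values were seen, with 267 counts in L. fuelleborni tooth and 0 in the other 3 groups (adjusted p = 5.49e-06). With edgeR, 1 gene passed without L. fuelleborni taste bud replicate 4 and 2 without a filter. Of the 2 without a filter, LOC105940538 had all its 337 M. zebra taste bud counts in 1 library. The other, LOC105941002, had 0 counts in M. zebra taste bud. Of the 10 lists tested, the oral keratinocyte list passed the camera test (adjusted p = 0.0404). Its median log2FC was -2.96 in L. fuelleborni and -2.04 in M. zebra, and adjusted p = 0.683 with an estimated correlation. With the replicate number as a random block the list did not pass in pre-ranked camera, as the smallest adjusted p of any list was 0.0566. Test and model both differed there, so this cannot be put down to the block alone. The call ended in 9 of the 12 fits that left out a library (adjusted p 0.0577 to 0.271), all but those without L. fuelleborni taste bud replicate 2 or M. zebra taste bud replicates 1 or 3. Those fits tested 12 to 13 lists, and over the same 10 lists the call ended in 7, as it then held without L. fuelleborni tooth replicates 3 or 4 (0.0481 and 0.0482).

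The species were next compared within tooth. Both species were counted over the same features, and reads of one species may map to a feature less well than those of the other. This was not tested, and it limits every gene named in the species comparisons of tooth and taste bud. The DNA repair gene smc6, a member of the SMC5/6 complex, had the largest fold of the genes named for this comparison, at 12496 ± 5289 CPM (SD, n = 3) in L. fuelleborni and 61.4 ± 36.8 in M. zebra, 179.6-fold higher (log2FC 7.65, SE 0.72, adjusted p = 1.52e-07). Other genes higher in L. fuelleborni were pdpr, 18.8-fold (adjusted p = 1.69e-04), tgds, 8.50-fold (adjusted p = 0.0165), and cdk5rap1, with 114 counts against 1 and a ratio of 118 (20.8 to 4705). Higher in M. zebra were the chaperonin-like gene mkks, 81.9-fold (log2FC -6.28, SE 0.68, adjusted p = 6.84e-07), tram2, 14.6-fold (adjusted p = 0.00552), and svop, 5.42-fold (adjusted p = 0.0192). In all, 45 genes passed, 23 higher in L. fuelleborni and 22 higher in M. zebra. Of the fixed lists, only the immune list held a called member, and 0 of 10 lists passed the camera test with the preset or the estimated correlation. Without L. fuelleborni tooth replicate 4, the tooth mineral matrix list passed the camera test with the preset correlation, lower in L. fuelleborni (adjusted p = 9.33e-04, against 0.955 with it). The estimated correlation between its genes was 0.556 with all libraries, above the preset 0.01, and was not used in that fit. That p-value may therefore be too small.

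The ribosomal protein share was 3.68% ± 2.27 in L. fuelleborni tooth and 2.11% ± 0.418 in M. zebra tooth (exact permutation test, two-sided, p = 0.3, where the smallest possible is 0.1). Of the 65 ribosomal protein genes, 1 was called higher in L. fuelleborni tooth, and 62 had a positive log2FC, with a median of 1.23. With this share as a covariate the calls of tram2 and svop ended (adjusted p = 0.101 and 0.0917). The log2FC of tram2 was then -3.74 (SE 0.97) against -3.83 (SE 0.76) without the covariate, and that of svop -2.06 (SE 0.55) against -2.32 (SE 0.54). The number of calls in tooth was 29 with the covariate, 27 without L. fuelleborni tooth replicate 4, 91 without L. fuelleborni taste bud replicate 4 and 124 without a filter, with 2962, 3396, 3684 and 20692 genes tested. Single genes lost their call in some fits that left out a library: tgds in 4 (adjusted p 0.0530 to 0.0928), those without L. fuelleborni replicate 4 or M. zebra replicates 0, 1 or 3; svop in 4 (0.0517 to 0.147), those without L. fuelleborni replicates 0 or 4 or M. zebra replicates 1 or 3; and tram2 in 2 (0.0690 to 0.0805), those without L. fuelleborni replicate 4 or M. zebra replicate 1.

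In taste bud, smc6 again had the largest ratio of the genes named, with 13972 counts in L. fuelleborni and 3 in M. zebra, a ratio of 2202 (753 to 10679). The genes tgds and cdk5rap1 had 87 and 49 counts in L. fuelleborni and 0 in M. zebra, at least 13.7-fold and 7.72-fold higher. With 1 count in M. zebra, the ratio was 37.4 (6.51 to 1494) for the intramembrane protease gene sppl2b. Higher in M. zebra were scarf1, 29.0-fold (log2FC -4.64, SE 0.74, adjusted p = 2.99e-04), tbl3, 15.4-fold (adjusted p = 0.00158), vwc2, 14.8-fold (adjusted p = 0.00314), blcap, 14.4-fold (adjusted p = 0.00362), and galnt11, an enzyme of mucin-type glycosylation, with 1 count in L. fuelleborni and 40 in M. zebra, a ratio of 84.6 (14.3 to 3424). In all, 127 genes passed, 60 higher in L. fuelleborni and 67 higher in M. zebra. Without M. zebra taste bud replicate 2 the calls of blcap (log2FC -1.91, adjusted p = 0.177) and galnt11 (log2FC -4.86, adjusted p = 0.0550) ended, and the log2FC of sppl2b was 7.69 without M. zebra taste bud replicate 3, against 4.98 with all libraries.

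Ribosomal protein genes made up 17 of the 60 genes higher in L. fuelleborni taste bud, 64 of the 65 had a positive log2FC, and their median was 1.64. Their share of counts was 4.50% ± 1.69 in L. fuelleborni and 1.71% ± 0.392 in M. zebra taste bud (exact permutation test, two-sided, p = 0.1, the smallest possible), and over both tissues, permuted within tissue, the species differed with exact p = 0.015. With this share as a covariate, 28 genes passed in taste bud and the calls of galnt11, blcap, tbl3 and vwc2 ended (adjusted p = 0.458, 0.382, 0.0540 and 0.0822). The log2FC moved towards 0 for galnt11, to -4.17 (SE 1.95) from -5.97 (SE 1.11), and for blcap, to -3.26 (SE 1.36) from -3.99 (SE 0.81). It moved away from 0 for tbl3, to -5.04 (SE 1.22) from -3.97 (SE 0.74), and for vwc2, to -5.45 (SE 1.45) from -3.84 (SE 0.77). The SE of all 4 was larger with the covariate. Without the 3 libraries of highest ribosomal share, galnt11 and blcap missed the threshold (adjusted p = 0.117 and 0.106), with log2FC of -4.24 (SE 1.47) and -3.75 (SE 1.26). The number of calls was 81 in a fit on taste bud libraries only, 64 without M. zebra taste bud replicate 2, 212 without L. fuelleborni tooth replicate 4, 230 without L. fuelleborni taste bud replicate 4 and 229 without a filter, with 1383, 3728, 3396, 3684 and 20692 genes tested, against 2962. None of the 10 lists passed the camera test, and the oral keratinocyte list had the smallest adjusted p (higher in L. fuelleborni, adjusted p = 0.0537, and adjusted p = 0.686 with an estimated correlation). It passed without L. fuelleborni taste bud replicates 2 or 4 or M. zebra taste bud replicates 1 or 3 (adjusted p 0.0135 to 0.0425).

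Genes that differed between species in one tissue were compared with those in the other. Of the 23 and 60 genes higher in L. fuelleborni in tooth and in taste bud, 20 were the same, smc6, tgds and cdk5rap1 among them, against 0.466 for independent lists. Of the 22 and 67 genes higher in M. zebra, 18 were the same, against 0.498. A difference in mapping between the species would be shared by the tissues as well, and was not tested. Among genes called in either tissue, 112 of 134 (83.6%) had the same direction. Across all 2962 genes the species log2FC correlated less between tissues, with Pearson's r = 0.48 and Spearman's rho = 0.22.

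Finally, genes detected in both tissues were counted, since the study sets tooth and taste bud renewal side by side. At 1 CPM or more in all 12 libraries there were 2332 genes. Another 384 genes were at or above 1 CPM in all 6 tooth libraries and below it in all 6 taste bud libraries, and 21 showed the opposite. At this depth 1 CPM amounted to at least 1 count, so these numbers measure detection and depend on depth. M. zebra taste bud was the shallowest group. In all 6 tooth libraries 6216 genes reached 1 CPM, and in all 6 taste bud libraries 3011 did. Of the 2332 shared genes, 1773 were tested, and 667 of those differed between tissues (259 higher in tooth, 408 higher in taste bud). The set leaves out every gene without a count in some taste bud library. Its direction is therefore not comparable with that of all tested genes, of which 967 were higher in tooth and 597 in taste bud. At 50 CPM, chosen after seeing the data, 646 genes were shared.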

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

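Leaving out the 3 libraries of highest ribosomal share and setting aside tgm1 were chosen only after the result was seen. A difference between the species in their tissue difference singled out 1 result. The oral keratinocyte list passed the camera test of that difference (adjusted p = 0.0404). Its median log2FC of tooth over taste bud was -2.96 in L. fuelleborni and -2.04 in M. zebra. With the replicate number as a random block and the pre-ranked form of camera, the call ended, as the smallest adjusted p of any list was 0.0566. The test changed along with the model, so the loss cannot be put down to the block alone. For tgm1, with no tooth count in either species, the difference is not defined. Of the other 11 tested members, 9 had a more negative value in L. fuelleborni, with a median difference of -0.99, and without tgm1 the camera test gave adjusted p = 0.0373. None of the 12 tested members passed edgeR's test, and the smallest adjusted p among them was 0.493, for esrp1. With an estimated correlation adjusted p was 0.683, with fry it was 0.317, and without the 3 libraries of highest ribosomal share it was 0.476. Leaving out a library ended the call in 9 of 12 fits (adjusted p 0.0577 to 0.271), all but those without L. fuelleborni taste bud replicate 2 or M. zebra taste bud replicates 1 or 3. These fits tested 12 to 13 lists, and over the same 10 lists the call ended in 7 (adjusted p 0.0549 to 0.339). Groups of 3 libraries were not tested for outlying libraries.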

How the results depend on the processing

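Leaving out the 3 libraries of highest ribosomal protein share, that share as a covariate and the 50 CPM threshold were chosen only after the data were seen. Of the comparisons of named genes with alternatives, 2350 kept their side of the threshold, 75 lost the call, 21 gained one and 1 reversed. Of those of list tests, 679 kept their side, 19 lost and 22 gained the call. A change of direction counted as a reversal only where either fit passed. Those that kept their side therefore include changes of direction where neither fit passed, as for jag1. Without a filter on low counts, 3327 genes passed in the tissue comparison of both species, 1881 in L. fuelleborni, 124 in the species comparison of tooth, 229 in that of taste bud and 2 in the test of the difference between species. With at least 1 CPM in 3 libraries these were 3506, 1898, 105, 274 and 3. Both settings tested more genes (20692 and 16529 against 2962). For the difference between species, limma-voom and the random replicate block each called 1 gene, and the cause was not tested. A fit on the compared libraries only called 81 genes between species in taste bud, with 1383 genes tested. The share of tissue calls higher in tooth was 61.8% with TMM, 67.3% with RLE size factors and 70.9% with library size alone.

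Without the 3 libraries of highest ribosomal share, 744 genes passed between tissues in L. fuelleborni and 18 in the test of the difference between species, and of the 17 lists then tested, 6 passed between tissues, 1 between species in tooth, 1 in taste bud and 0 for the difference. L. fuelleborni taste bud then held 1 library, assumed to vary like the other groups. The immune gene cd74 then reversed, with a log2FC of -1.18 between tissues (adjusted p = 0.0364). With the share as a covariate, 29 genes passed between species in tooth and 28 in taste bud. The causes were not tested. At 50 CPM, 646 genes were expressed in both tissues. Of 10 lists, 0 passed between tissues with an estimated correlation and 10 with fry, which compares a list with no other genes. For the difference between species, 0 lists passed with an estimated correlation, 0 with fry and 0 with the random replicate block in pre-ranked camera.

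With each library left out in turn, calls ranged from 1647 to 1937 in the tissue comparison of both species, 1027 to 1387 in L. fuelleborni, 1089 to 1519 in M. zebra, 27 to 91 between species in tooth, 64 to 230 in taste bud and 0 to 1 for the difference between species. List calls ranged from 4 to 6 between tissues and from 0 to 1 in tooth, in taste bud and for the difference between species. Genes expressed in both tissues ranged from 2343 to 2971. All fits that left out a library, of the compared groups or not, tested more genes (3396 to 3728 against 2962) and lists (12 to 13 against 10).

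Whether the replicate numbers pair the libraries is not given in the labels, and they were not treated as pairs. Deviations of same-numbered libraries correlated at -0.0075 for L. fuelleborni 4, 0.052 for M. zebra 1 and 0.236 for M. zebra 3. Those of M. zebra 1 and of M. zebra 3 correlated best with each other, a hint from the data and not from the design, and those of L. fuelleborni 4 did not. With the replicate block, 1605 genes passed between tissues as a random and 1322 as a fixed term. Of simulated 4-fold changes, 34.3% were recovered between species in tooth and 35.8% in taste bud, against 82.1% between tissues over both species. No simulation varied depth, so its part in this was not tested.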

Other observations

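All gene families in this part, the makeup of the split with the most calls and the tests of the ribosomal, strand and feature explanations were chosen only after the values were seen, except the thinning to low depth and the effect of the abundant feature on the tissue calls, whose bounds were set before their results. Further matrix genes were higher in tooth. Of 15 collagen chain genes tested, 3 of them also in the tooth mineral matrix list (col1a1, col1a2 and col10a1), 13 were higher in tooth and 2 did not pass, col28a1 (adjusted p = 0.457) and col6a6 (adjusted p = 0.275). Of the 12 outside that list, 10 were higher in tooth. Basement membrane collagen col4a2 had 123 counts in tooth and 5 in taste bud (log2FC 3.74, SE 0.69), and col11a1 had 331 and 6. The camera test of the 15 gave adjusted p = 1.38e-04, and adjusted p = 0.200 with an estimated correlation. Single matrix genes picked after their values were seen, which test no group, were higher in tooth as well. They were the collagen chaperone gene serpinh1 (log2FC 4.55, SE 0.72, adjusted p = 6.95e-06), the proteoglycan gene decorin, dcn (log2FC 5.28, SE 0.55, adjusted p = 1.29e-08), and the matrix protease gene mmp2 (log2FC 4.40, SE 0.57, adjusted p = 3.43e-07).

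In taste bud, genes known from meiosis that were picked in the same way were higher: sycp1, syce1 (log2FC -2.87, SE 0.40) and tex11 (log2FC -2.92, SE 0.47). Of 5 integrin genes, itga1, itgav, itgb3 and itgb5 were higher in tooth and itgb4, a partner in hemidesmosomes, was higher in taste bud (log2FC -1.88, SE 0.52, adjusted p = 0.00307). Of 28 solute carrier genes, 8 were higher in tooth, 6 in taste bud and 14 did not pass, and with library size alone these were 9, 4 and 15, with RLE size factors 8, 4 and 16. The counts of the other families were the same under these 3 scalings.

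Ribosomal protein genes ranked low. Their median rank was within the top 1% of the features in 2 of 12 libraries, a bound set after the ranks were seen. Reads counted on the strand opposite to the transcript could give such ranks. This count restates the low ranks and cannot decide on that explanation. Low depth as the whole cause was argued against, since the best ranked tooth and taste bud libraries, thinned to 72226 counts, had mean median ranks of 168 and 126, inside the bound of 264.9. The strand setting stays open, and no biological explanation was tested.

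Ribosomal protein genes were higher in L. fuelleborni than in M. zebra taste bud, by a median log2 difference of 1.64. The abundant feature LOC105941146 did not account for it, since without it the ratio of mean shares was 2.73, against 2.63 with it. A factor that moves many genes between libraries of one group may contribute. Outside the ribosomal list, 32 genes rose with the share within groups. Their median log2 difference was 1.68 in taste bud (1.32 to 1.86 in a bootstrap over genes), though only 0.43 in tooth. Genes that vary together are not independent, and libraries were not resampled, so the interval does not measure the spread between libraries. A difference between the species stays open as untested.

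The tissue difference was tested against the same explanations. Of the 1564 genes called, 1555 also passed with the log2 ribosomal share in the model. That share was similar in tooth and taste bud (3.68% and 4.50% in L. fuelleborni, 2.11% and 1.71% in M. zebra). The model could therefore remove few tissue calls in any case, and it does not decide. With LOC105941146 left out, 1508 of the genes called also passed, so that this feature could not be the whole cause. Of 100 splits of the libraries drawn from 200, 1, the real one, gave as many calls as the real 1564. The highest other gave 194, which makes random grouping of the libraries unlikely for this count. The smallest share that these splits could give was 1 of 100. For the comparisons with 10 splits (3 libraries against 3), the splits were too few for a share under 0.05. The real counts were 1142 and 1262 between tissues in L. fuelleborni and M. zebra and 45 and 127 between species in tooth and taste bud, with 0 as the highest other in each, and 1 of the 10 splits reached the real count. For the difference between species the real count was 0 (edgeR, with 228 genes at an unadjusted p under 0.05, 0 calls by DESeq2 and 1 by limma-voom). All 100 of 100 splits reach a count of 0 by construction, so the splits decide nothing there. The highest other split called 58 genes, which points to a structure of the samples. Its contrast set 5 of the 6 M. zebra libraries, with L. fuelleborni tooth replicate 3, against 5 of the 6 L. fuelleborni libraries, with M. zebra tooth replicate 0. Of its 58 genes, 49 were among the 134 called between species in tooth or taste bud, against 2.62 for independent lists, so that the structure was largely the species difference.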
